A study of Homo sapiens with 6 samples.

How the data were processed

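The data are the processed values of 6 Affymetrix Human Genome U133 Plus arrays, hybridised with biotin-labelled total RNA of HCT116 cells. Per the submitters' processing notes, the authors used RMA and Partek, whose versions and settings are not given in the sources used here. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a probe set. The deposited values were taken as log2 values: they lay between 1.47 and 13.6 on every array with medians from 3.41 to 3.53, which fits a log scale, while base 2 is the usual output of RMA and is not stated. Quantile scaling of this kind removes a shift shared by most genes, so that only differences relative to the bulk of genes can be seen. RMA reads each probe set as one number, so a loss of signal from part of a transcript shows as a lower level in the probe sets that lie there.

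Probe sets were named through the array annotation given with the series. Of 54675 probe sets, 41091 had 1 gene symbol, 1801 had several and 11777 were not listed with a gene. The 62 control probe sets were left out of all fits. Symbols were looked up by gene identifier in the RefSeq gene table, and 0 were changed. Each of the 19775 genes was represented by its probe set with the highest mean over the 6 arrays. No array coordinates are printed, because the array values name no genome build, and matches to the miR-224 seed in 3′ UTRs were not analysed here.

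Groups were taken from the sample titles, which number the control and the miR-224 cells 1 to 3. The series states that the pairs come from 3 independent experiments, so equal numbers were read as one experiment. Deviations from the group means correlated across genes, which are not independent replicates, between same-numbered arrays at 0.855, 0.585 and 0.771 for experiments 1, 2 and 3, and between arrays of different number at -0.753 to 0.257, so the numbers pair the arrays. Results with experiment as a block are given where they change a call.

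Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05), without the block in the main analysis, which leaves 4 residual degrees of freedom, 2 with the block and 1 with experiments 2 and 3 only. Standard errors of log2 differences are those of the moderated fit. Without the block they take in differences between experiments. With experiments 2 and 3 only, they draw on variances pooled over genes, as 1 residual degree of freedom is left. Lists were compared with camera (preset correlation 0.01, Benjamini-Hochberg over 30 lists), and again with an estimated correlation and with fry. fry tests whether a list's genes move one way on balance, and does not compare them with other genes. The lists hold 822 genes, of which 757 were measured, and cover reported miR-224 targets, signalling, cell cycle, stress, metabolic and differentiation genes, and 5 lists of markers of other cells. They were written from memory, and they, the tests and most alternatives were set before the data were examined. The alternatives were the block, each array left out, only genes at or above the median level, another quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, other variance settings, other thresholds and a plain t statistic. Alternatives that combine the block with leaving out experiments, variance settings, array weights or another choice of probe set were added after the data were seen.

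The genes named are the 12 that rose and the 12 that fell most past the threshold, with a mean in the higher group of at least the median of all genes (4.75) and the same sign in every experiment. As none passed, both lists were filled by smallest unadjusted p of the fit without the block. The rule also takes the reported targets, the host gene GABRE and up to 4 members of each list that passed, by smallest p of the same fit. Of the 26 targets, 25 were measured, and neither EDNRA nor GABRE was analysed here.

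The fits were tested on simulated data with 200 changed genes among 19775, drawn with the variances of the blocked fit and the same effect in each experiment. Without the block, 8% of genes changed by 1 on the log2 scale were recovered and 69% of those changed by 2, with 0 false calls. With the block, 100% of both were recovered with 20 false calls, and with experiments 2 and 3 alone 100% with 29 false calls, so that both blocked fits made more false calls than the threshold of 0.05 implies. Because the simulated effect did not vary between experiments, the recovery is an upper bound. In a simulation of 30 lists, camera called the moved list and 0 of the others. The simulated genes varied independently and the lists were random, so it cannot show whether genes that vary together give false calls. Bootstrap intervals are at 95% with 2000 draws over genes, taken as independent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.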

Results

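HCT116, an established human colon carcinoma line with wild-type p53, received control oligos or a precursor of miR-224, each at 50 nM, and total RNA was taken after 24 h. The data are 6 Affymetrix expression arrays, 3 control and 3 miR-224, which the series describes as pairs from 3 independent experiments. Each array gave expression values for 54675 probe sets, read here as log2 although their base is not stated, and 19775 genes were compared by the brightest probe set of each gene. With 3 arrays in each group, the number of arrays limits the precision. The comparison asks which transcripts differ when cells are given miR-224, a microRNA that pairs with sites in messenger RNAs and lowers their level or translation.

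The arrays grouped by experiment before they grouped by treatment. The first principal component held 71.0% of the variance and set both arrays of experiment 1 apart from the other 4, while the third component (8.45%) separated miR-224 from control within every experiment. The control probe sets for actin and GAPDH, which read the 3′ and the 5′ part of each transcript, also set experiment 1 apart. The actin probe set at the 5′ end read 4.28 on average in experiment 1 and 12.4 in experiments 2 and 3, whereas the one at the 3′ end read 12.5 in both. For GAPDH the 5′ values were 4.10 and 13.0, and the 3′ values were 12.8 and 13.1. Both arrays of experiment 1, control and miR-224, had this low 5′ signal, so it is balanced between the groups, and it bears on every value from experiment 1 given below.

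**Figure D1:**
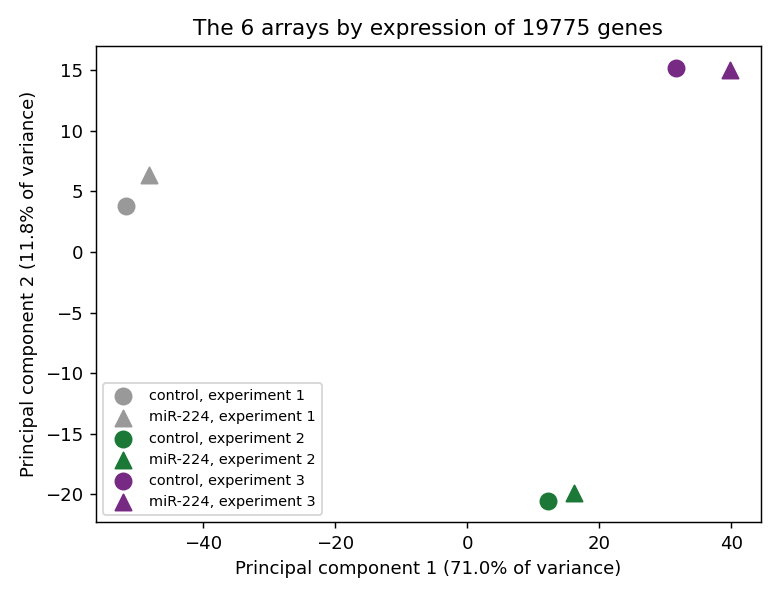
The 6 arrays on the first and second principal components of the expression of 19775 genes, with the share of variance on each axis, circles for control, triangles for miR-224 and a colour for each experiment. The arrays of each experiment lie side by side, and those of experiment 1 lie at the far left, at -51.6 and -48.2 on the first component.

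Genes reported in the literature as direct targets of miR-224 were lower as a group in the miR-224 cells. Of 25 measured genes on the list, 20 had a lower mean, with a median log2 difference of -0.26, which was -0.16 without control replicate 2 and also -0.16 with the mean of a gene's probe sets. The largest differences were those of API5, an inhibitor of apoptosis (-1.08 ± 0.48 SE), CDKN1A, which encodes the cell cycle inhibitor p21 (-0.95 ± 0.61), RASSF8, of the RAS association domain family (-0.94 ± 0.34), SMAD4, the shared mediator of TGF-beta signalling (-0.79 ± 0.28), and PPP2R1B, a scaffold subunit of protein phosphatase 2A (-0.76 ± 0.48). These standard errors are of the fit without experiment as a block and take in differences between experiments. With the block they were 0.19 for API5, 0.15 for CDKN1A, 0.10 for RASSF8, 0.23 for SMAD4 and 0.13 for PPP2R1B. CDKN1A stood at -0.54, -0.96 and -1.35 in experiments 1, 2 and 3. GSK3B, a kinase of WNT and insulin signalling, was lower by a similar amount in each experiment, at -0.37, -0.47 and -0.50 in experiments 1, 2 and 3, while TRIB1 was lower in each by unequal amounts, at -0.28, -0.20 and -0.45. Each value is that of the gene's brightest probe set, and others at or above the median level differed less. They stood at -0.17 and -0.69 for API5, -0.32 and -0.26 for PPP2R1B and -0.12 for SMAD4. For GSK3B and TRIB1 they stood at -0.15 and -0.08. The other probe sets of RASSF8 were dim and stood at 0.18, -0.18 and -0.04. The list passed the set test (limma's camera, preset correlation, adjusted p = 3.1e-06 over 30 lists), and its median was negative in each experiment, at -0.10, -0.19 and -0.42. The call was lost with an estimated correlation between genes (adjusted p = 0.12) and with fry (adjusted p = 0.35, unadjusted p = 0.012). The list was recalled from the literature, and whether these arrays served to choose any of its members is not known here.

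No single target passed the test, neither over all genes (lowest limma adjusted p = 0.9999) nor adjusted over the list alone, where 0 passed and 4 had an unadjusted p under 0.05 (RASSF8, SMAD4, GSK3B and TRIB1). With experiment as a block the list passed again (adjusted p = 6.5e-08, and 0.72 with an estimated correlation), and 10 targets fell when adjusted over the list alone (API5, CDKN1A, RASSF8, SMAD4, PPP2R1B, KLK10, DPYSL2, NCOA6, GSK3B and TRIB1), and 0 passed over all genes. In blocked fits added after the data were seen, 4 targets passed over all genes with an intensity trend and robust variances (adjusted p = 0.0062 for CDKN1A, 0.0072 for RASSF8, 0.018 for API5 and 0.028 for PPP2R1B), and RASSF8 passed with array weights (0.047). Without the block, leaving out single arrays moved several of the 10 targets by more than 1.5 times, though none of the 10 changed sign. Other reported targets did change sign, as given in the part on processing. Leaving out an array breaks a pair and so lets differences between experiments into the group means. Without miR-224 replicate 1 the difference was -1.63 for API5, -0.56 for CDKN1A, -1.22 for PPP2R1B, -1.22 for DPYSL2 and -0.97 for NCOA6. Without miR-224 replicate 3 it was -0.38 for PPP2R1B, -0.24 for DPYSL2, -0.30 for NCOA6 and -0.53 for SMAD4, and without miR-224 replicate 2 it was -0.35 for NCOA6. Without control replicate 1 it was -1.55 for CDKN1A, -0.48 for PPP2R1B and -0.42 for DPYSL2, and without control replicate 3 it was -0.47 for CDKN1A and -0.43 for KLK10. Several targets were closer to 0 in experiment 1, a difference between experiments that was not tested gene by gene. API5 was lower by -0.38, -1.39 and -1.46 in experiments 1, 2 and 3, and DPYSL2 by -0.10, -1.03 and -0.89. The serine protease gene KLK10 stood at 0.06, -0.70 and -1.51, and the nuclear receptor coactivator NCOA6 at 0.05, -0.94 and -0.73. SMAD4 was lowest in experiment 3, at -0.28, -0.40 and -1.70. RASSF8 was lower by similar amounts throughout, at -0.93, -1.03 and -0.86, but its level was low, with a control mean of 4.21 ± 0.52 (SD, n = 3) against a median of 4.75 over all genes. Targets that showed little difference included PEBP1 (0.05 ± 0.17), PAK4 (-0.02 ± 0.10) and CAV1 (-0.06 ± 0.16). YY1 was higher by 0.21 ± 0.22, and by 0.04 to 0.36 without single arrays, while its probe sets differed in sign. EDNRA and GABRE, the host gene of miR-224, were not analysed here.

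**Figure D2:**
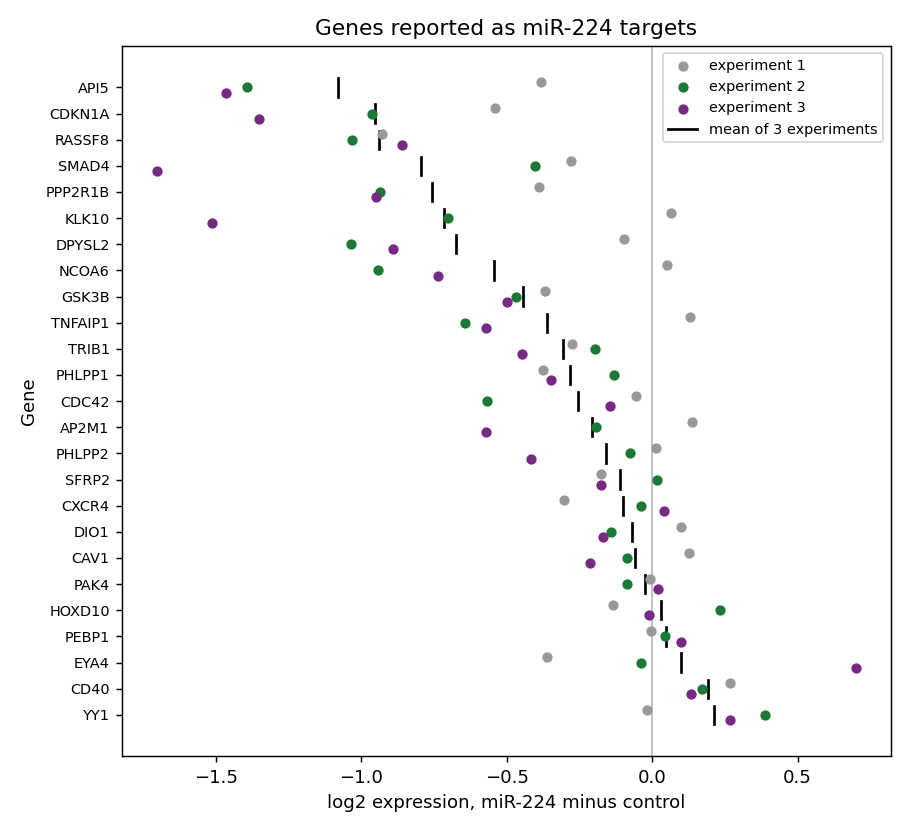
Log2 expression in miR-224 minus control cells for the 25 measured genes reported as miR-224 targets, with a dot for each experiment (grey 1, green 2, purple 3) and a black bar for the mean of the 3 experiments. The mean lies below 0 for 20 genes, and the grey dots of API5, KLK10, DPYSL2 and NCOA6 lie nearer to 0 than the others.

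Across all genes, no transcript passed the test between the 3 miR-224 and the 3 control arrays. The genes given here had the smallest p of the fit without experiment as a block, among those with the same sign in every experiment. A choice by the blocked fit would differ. FRMD8 (-1.62) and NUP58 (-1.69) are not among them, with a blocked limma adjusted p of 0.086 and 0.105. Their standard errors are of the fit without experiment as a block and take in differences between experiments. Lower in the miR-224 cells were SLC17A5, a lysosomal sialic acid transporter (-1.50 ± 0.37 SE on the log2 scale), ITPRIPL2 (-0.99 ± 0.29), ZNF395 (-0.96 ± 0.24), SDC4, the cell-surface proteoglycan syndecan-4 (-0.89 ± 0.25), UBN2 (-0.82 ± 0.20), and UBE2J1, a ubiquitin-conjugating enzyme of the endoplasmic reticulum (-0.70 ± 0.20). CDK19, a kinase of the Mediator complex, was lower by -0.51 ± 0.12, ABL2 by -0.45 ± 0.13, GSK3B by -0.44 ± 0.12, CLEC16A by -0.42 ± 0.11, PAN2, a subunit of a poly(A) nuclease, by -0.40 ± 0.10, and SFTPB by -0.40 ± 0.11. Higher were YWHAH, a 14-3-3 protein (0.95 ± 0.30), the pseudokinase gene TRIB2 (0.72 ± 0.18), EEIG2 (0.71 ± 0.20), PRRC2B (0.58 ± 0.19), the homeobox gene MSX1 (0.55 ± 0.18), HS6ST1 (0.53 ± 0.17), ALYREF, an mRNA export factor (0.52 ± 0.12), LOC285847 (0.50 ± 0.12), KIR2DS5 (0.44 ± 0.11), ASPDH (0.41 ± 0.11), CALU (0.40 ± 0.12) and HR (0.36 ± 0.12). All 24 missed the threshold, with an adjusted p of 0.9999 and, with experiment as a block, of 0.086 (SLC17A5) to 0.28 (HR). In the blocked fit with an intensity trend and robust variances, added after the data were seen, 8 of them passed, with an adjusted p of 0.0062 for SLC17A5, YWHAH and ITPRIPL2, 0.015 for SDC4, 0.018 for ALYREF, 0.020 for ZNF395, 0.028 for EEIG2 and 0.039 for MSX1. Among the 19 that have several probe sets, 1 held another bright one of the opposite sign. Dimmer ones differed too. SFTPB had others under the median level at 0.28, 0.20 and -0.03, and it reversed with the mean of its probe sets. CLEC16A had a dim one at 0.38, and LOC285847 had dim ones at 0.12 and 0.06.

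The limma fit called 0 genes at an adjusted p under 0.05, and 313 had an unadjusted p under 0.05 (194 higher, 119 lower), fewer than the 989 expected if no gene differed and the arrays were independent, which the paired arrays were not. With experiment as a block, it again called 0 (lowest adjusted p = 0.086), with 2169 at an unadjusted p under 0.05, more than the 989. An intensity trend and robust variances in the blocked fit, added after the data were seen, gave 56 genes, of which 15 rose and 41 fell. At an adjusted p under 0.1 the blocked fit called CHPF, which was higher by 0.83, 0.84 and 1.11 in experiments 2, 3 and 1, and RASSF8, SLC17A5 and FRMD8, which were lower. The same 4 genes passed at 0.05 when the blocked fit weighted the arrays. CHPF and FRMD8 were singled out after their values were seen, as were the genes of experiments 2 and 3 given below other than SLC17A5, YWHAH and the reported targets.

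Experiments 2 and 3 alone, fitted with experiment as a block, gave 174 genes, of which 147 fell and 27 rose. This fit was chosen after the data were seen, because experiment 1 stood apart, and it leaves 1 residual degree of freedom per gene. Its count depended strongly on processing, from 7 genes with the mean of a gene's probe sets to 491 among genes at or above the median level. The genes that fell most were TMC5 (-2.06 ± 0.19 SE), NUP58, a nuclear pore component (-2.05 ± 0.19), FRMD8 (-1.99 ± 0.14), SLC17A5 (-1.82 ± 0.14), SUMF1, the activator of sulfatases (-1.77 ± 0.14), NECAP1, a clathrin-associated protein (-1.73 ± 0.14), EIF5A2 (-1.61 ± 0.18) and SIKE1 (-1.56 ± 0.13). Among those that fell were 7 of the reported targets, namely API5 (-1.43 ± 0.13), CDKN1A (-1.16 ± 0.15), KLK10 (-1.11 ± 0.18), DPYSL2 (-0.96 ± 0.14), RASSF8 (-0.95 ± 0.14), PPP2R1B (-0.94 ± 0.13) and NCOA6 (-0.84 ± 0.14). All these values are those of a gene's brightest probe set. Of the 131 called genes with several probe sets, 11 held another bright one of the opposite sign over all 6 arrays. Sizes differed as well. Over all 6 arrays NUP58 stood at -1.69 on the probe set used and at -0.80 and -0.13 on other bright ones. TMC5 stood at -1.46 and -0.19, and SLC17A5 at -1.50 and -0.92. SAR1B, which rose and is among those 11, stood at 0.85 on the probe set used and at 1.21, 0.37 and -0.05 on other bright ones. Genes that rose included THG1L (1.48 ± 0.22), SAR1B (1.14 ± 0.22), YWHAH (1.03 ± 0.17), ARRDC4 (0.99 ± 0.14), GNB1 (0.99 ± 0.14), QKI (0.97 ± 0.15) and FOS (0.93 ± 0.15). With 1 residual degree of freedom, these standard errors draw on variances pooled over genes and need not show how far the experiments differ. In experiments 2 and 3, TMC5 stood at -2.50 and -1.63 and NUP58 at -2.48 and -1.61. KLK10 stood at -0.70 and -1.51 and THG1L at 2.04 and 0.91, whereas SIKE1 stood at -1.53 and -1.58.

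Experiment 1, which took no part in that fit, gave a check of direction. Of the 147 genes that fell, 121 (82.3%) were lower in experiment 1 as well, against 46.6% of all genes, but their median difference there was -0.22 (95% bootstrap interval -0.25 to -0.15), compared with -0.89 in experiment 2 and -0.83 in experiment 3. Of the 27 that rose, 21 (77.8%) were higher in experiment 1, against 53.1% of all genes, with a median of 0.24 (0.01 to 0.37). The bootstrap treats genes as independent, which they are not. Of the 147 and 27 genes, 38 and 9 also passed over all 6 arrays when the blocked fit used an intensity trend and robust variances. That fit, added after the data were seen, includes the arrays on which these genes were chosen, so the overlap is not an independent check. Leaving out experiment 2 or experiment 3 in place of experiment 1 gave 0 genes in each case.

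**Figure D3:**
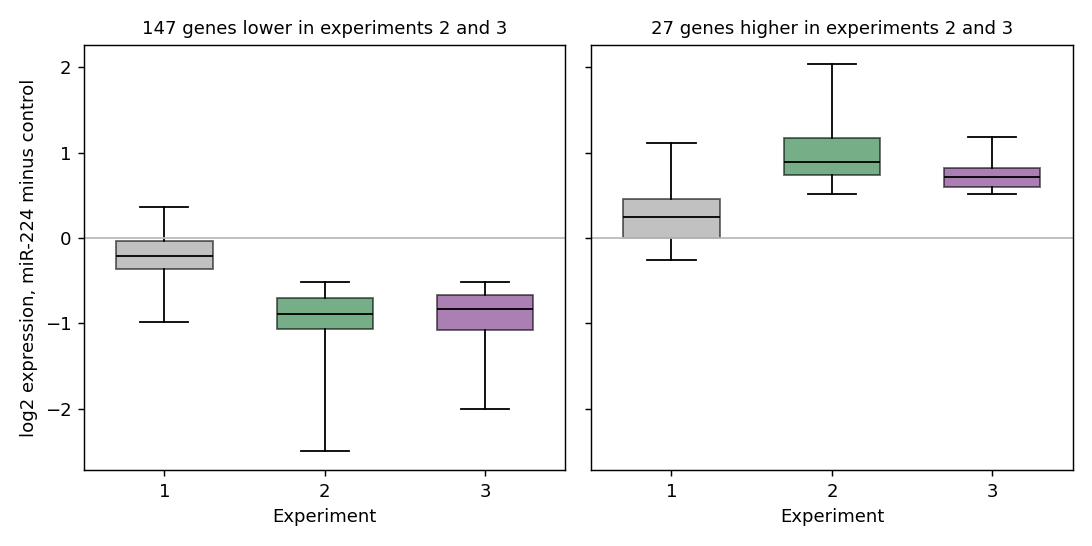
Log2 expression in miR-224 minus control cells, by experiment, for the 147 genes lower and the 27 genes higher in experiments 2 and 3, with boxes for the quartiles, lines for medians and whiskers to the lowest and highest gene. The genes were chosen on experiments 2 and 3, and the grey boxes of experiment 1, which took no part in the choice, have medians of -0.22 and 0.24.

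Among the gene lists fixed beforehand, genes of G2 and mitosis were higher as a group in miR-224 cells. Of 38 members 35 had a higher mean, with a median log2 difference of 0.15. The 4 members given next had the smallest p of the list without the block, and all lay above that median. PLK1, the mitotic kinase, was higher by 0.50 ± 0.23 (SE), KIF20A, a mitotic kinesin, by 0.56 ± 0.26, PRC1, which organises the central spindle, by 0.48 ± 0.27, and CCNB2, a B-type cyclin, by 0.36 ± 0.28. Single arrays moved 3 of these 4 by more than 1.5 times: PLK1 was 0.29 without miR-224 replicate 2, PRC1 was 0.75 without control replicate 1 and 0.28 without control replicate 2, and CCNB2 was 0.63 without control replicate 1 and 0.11 without control replicate 3. The median was 0.05, 0.09 and 0.31 in experiments 1, 2 and 3. The list passed camera (adjusted p = 0.032), and 0 members passed over all genes or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.87), and with single arrays left out, which breaks a pair, the median ranged widely. It was 0.33 without control replicate 1, 0.26 without control replicate 2 and 0.38 without miR-224 replicate 3, the call was lost without miR-224 replicate 1 (0.0565) and miR-224 replicate 2 (0.0713), and the median was -0.13 without control replicate 3. These values take in differences between experiments. The list was higher in experiment 1 than in experiments 2 and 3 by a median of 0.53. Its difference between experiments 2 and 3, which bears on the values without arrays of experiment 3, is not given here. With both arrays of an experiment left out and the block, the median stayed above 0, at 0.20 without experiment 1, 0.19 without experiment 2 and 0.0771 without experiment 3, where the call was lost (adjusted p = 0.080). With experiment as a block the list passed again (adjusted p = 2.9e-06, and 0.72 with an estimated correlation), and PLK1 and KIF20A rose when adjusted over the list alone. PLK1 passed over all genes in the blocked fit with an intensity trend and robust variances (adjusted p = 0.040).

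The other 28 lists did not pass (adjusted p from 0.082 to 0.85). With experiment as a block, 2 of them did, both downward and neither with an estimated correlation (adjusted p = 0.72 for both). Cholesterol synthesis (adjusted p = 0.020) had 14 of 19 members lower and a median of -0.16. Its median was -0.03, -0.14 and -0.27 in experiments 1, 2 and 3, and HMGCS1, which makes HMG-CoA, stood at -0.07, -0.52 and -0.60. TGF-beta and SMAD targets (adjusted p = 0.043) had 16 of 25 members lower and a median of -0.15. Their median was -0.009, -0.06 and -0.18 in experiments 1, 2 and 3, whereas CCN1, a secreted matricellular protein, stood at -0.45, -0.32 and -0.66. HMGCS1 and CCN1 had the smallest blocked p of their lists and were chosen after their values were seen. The p53 target list, to which CDKN1A also belongs, had 20 of 28 members lower with a median of -0.06 (adjusted p = 0.14). The interferon list, which double-stranded RNA can induce, had a median of -0.03 (adjusted p = 0.082) and 23 of 36 members lower. Lists of markers of fibroblasts, leukocytes, endothelium, hepatocytes and kidney lines had medians of 0.06, 0.05, 0.05, 0.04 and 0.01. For NF-kB and inflammatory genes (median 0.01) and genes of G1/S and DNA replication (median 0.03) the test pointed down while the median was above 0, and hypoxia and glycolysis genes had a median of 0.01 and a mean of -0.05. The number of lists that passed was 10 without control replicate 1, 4 without miR-224 replicate 1, 6 without control replicate 3 and 7 without miR-224 replicate 3.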

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

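The tests of control levels, of the agreement between probe sets and of the 3′ and 5′ control probe sets were set before their results were seen. All other tests in this part were chosen after.

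Of 13522 probe sets without a single gene symbol, which the comparison of genes left out and only the alternative with all probe sets included, 27 differed between miR-224 and control cells in experiments 2 and 3 at an adjusted p under 0.05 (limma, with experiment as a block, 54613 probe sets tested, 137 called in all). Of these 27 probe sets, 26 were lower and 1 was higher, and 21 had the same sign in experiment 1. The one with the smallest p was lower by -1.92 ± 0.13 (SE) in experiments 2 and 3 and by -0.37 in experiment 1. The genes they read are not named here.

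Experiment 1 differed from experiments 2 and 3 at 7038 genes (5293 higher, 1745 lower, with treatment in the model), compared with 1121 genes between experiments 3 and 2. Several of the largest differences were in abundant transcripts, among them ID1 (-6.48), PSMC3, a proteasome subunit (-4.83), and the keratin KRT8 (-4.17). On the control probe sets, the 3′ signal exceeded the 5′ signal in experiment 1 by 8.67 more than in the other experiments for GAPDH and by 8.16 more for actin, and a gene's 2 brightest probe sets hardly shared the difference of experiment 1 (Pearson r = 0.133 across 3935 genes, which are not independent replicates, 95% interval 0.105 to 0.161, against 0.61 for experiment 3 minus experiment 2). A change tied to single probe sets, through degraded RNA or another labelling reaction in experiment 1, is therefore a candidate explanation, and the arrays do not separate degradation from labelling because the poly-A spike-in probe sets read at most 3.33 on all of them. Cells of another type remain open: the largest median difference among 5 marker lists was -0.124, and their median levels in experiment 1, 3.26 to 4.12, lay under that of all genes (4.75), but the interval of the 8 kidney line genes reached 0.562, and another colon line was not tested.

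The miR-224 difference was smaller in experiment 1 than in experiments 2 and 3. The choice of genes on experiments 2 and 3 does not account for all of it: 200 genes chosen on experiment 2 alone had a median change in experiment 1 of 0.273 times that in experiment 3 (interval 0.195 to 0.345), and 200 chosen on experiment 3 alone had 0.255 times that in experiment 2 (0.141 to 0.388). A low reading in the control cells of experiment 1 does not account for it either. The genes that fell read higher there, by a median of 0.422 (0.313 to 0.564). The 63 of them whose control level lay within 0.5 still had a median of -0.168 in experiment 1. These are readings of single probe sets on arrays with low 5′ signal, so poorer signal in experiment 1 is not excluded. A weaker microRNA effect in the cells of experiment 1 may account for the smaller difference, since the genes that fell were lower there too (-0.217). However, the arrays do not measure miR-224. The 2 brightest probe sets of a gene also agreed less on the miR-224 difference in experiment 1 (r = 0.133) than in experiments 2 and 3 (0.52 and 0.5). A weaker effect and the low 5′ signal of experiment 1 therefore cannot be told apart.

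With 3 arrays against 3, 10 splits exist, too few for a share under 0.05. In limma the real split called 0 genes and the highest of the others 0, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 313, and 4 splits that set both arrays of experiment 1 on one side gave 1236 to 4633, which points to a structure of the samples by experiment. Among the splits that part every pair, the other 3 gave 77, 132 and 139. With experiment as a block there are 4 ways to swap arrays within experiments, again too few, and all 4 called 0 genes in limma, the real one included. The real one gave 2169 genes at an unadjusted p under 0.05 and the highest of the others 927.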

How the results depend on the processing

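Alternatives that combine the block with another choice, and all those for experiments 2 and 3, were chosen after the data were seen. In the 16 alternatives planned for the gene test, the limma count stayed at 0, with experiment as a replicate block and without each array included (67 to 2169 genes at an unadjusted p under 0.05, and 575 with a plain t statistic). All but the block itself were fitted without the block, where 8% of simulated genes changed by 1 on the log2 scale were recovered. Counts of 0 there do not show that no gene changed. With the block added to another choice, the count became 174 without experiment 1, 56 with trend and robust variances (15 higher, 41 lower), 4 with array weights, 4 at an adjusted p under 0.1 and 1 with the probe set brightest in experiment 1 (RARA, at 1.31, against -0.01 for the probe set used otherwise). It stayed at 0 without experiment 2, without experiment 3 and among genes at or above the median level. The 174 genes of experiments 2 and 3 became 491 among genes at or above the median level, 457 with trend and robust variances, 127 with the probe set brightest in experiment 1, 50 after another quantile normalization and 7 with the mean of probe sets, of which 156, 174, 119, 50 and 7 were shared. The cause was not tested. The number of lists that passed was 2, and it was 4 with the block, 1 with the mean of probe sets, 0 with an estimated correlation or fry, with or without the block, 7 with the block and without experiment 1, 1 with the block and without experiment 3, and 2 to 10 without single arrays. The cause was not tested. The reported targets stayed lower in all alternatives, at -0.31 to -0.16 without single arrays and -0.16 with the mean of probe sets. Their median of -0.26 was no longer past the threshold with an estimated correlation or fry, with or without the block (adjusted p from 0.12 to 0.72), which allow for genes that vary together. Without the block this shared variation includes differences between experiments, and with the block it rests on 2 residual degrees of freedom. The G2 and mitosis list lost its call in the same 4 alternatives (median 0.15), with the mean of probe sets (0.16, adjusted p = 0.05004), and with the block but without experiment 3 (0.0771), and ranged from -0.13 to 0.38 without single arrays. The cause was not tested. The block changed no other call of a list named here than cholesterol synthesis and TGF-beta and SMAD targets.
Of the 52 named genes, 0 passed under any alternative set beforehand, 16 passed with the block and without experiment 1, 13 with the block, trend and robust variances and 2 with the block and array weights. Some reversed, none of them past the threshold. With the mean of probe sets SFTPB was 0.0137, YY1 -0.0616 and PAK4 0.0045. With the block, CXCR4 was 0.0024 without experiment 1, HOXD10 -0.0708 and PAK4 0.0066 without experiment 2, and EYA4 -0.20 and CAV1 0.0207 without experiment 3. Without single arrays, CDC42 ranged from -0.80 to 0.19, CXCR4 from -0.28 to 0.0515, HOXD10 from -0.0431 to 0.10, PEBP1 from -0.0618 to 0.18, PHLPP1 from -0.59 to 0.0722, PHLPP2 from -0.43 to 0.20, EYA4 from -0.068 to 0.25, AP2M1 from -0.54 to 0.0246, CD40 from -0.24 to 0.58, CAV1 from -0.18 to 0.0447 and PAK4 from -0.0615 to 0.0028. The cause was not tested. The alternatives planned for seed matches in 3′ UTRs were not run. Signal over background limits dim genes such as RASSF8.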

Other observations

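The fit of experiments 2 and 3 alone, and the choice of the genes given here, came after the data were seen. Among the genes that fell in that fit were single members of other lists fixed beforehand, some of which had more members higher than lower over all 6 arrays. On the list of microRNA machinery, with 11 of 17 members higher, XPO5, which exports microRNA precursors from the nucleus, was lower by -0.79 ± 0.13 (SE) in experiments 2 and 3 and stood at -0.04 in experiment 1. On the list of hypoxia and glycolysis genes, with 17 of 31 members higher, PFKFB3, a regulator of glycolysis, and PDK1, a kinase that inhibits pyruvate dehydrogenase, were lower by -1.33 ± 0.13 and -1.04 ± 0.13, with -0.44 and 0.04 in experiment 1. CCND1, which encodes cyclin D1 and is on the lists of WNT/beta-catenin targets (19 of 27 members higher) and of MAPK feedback and early response genes (20 of 36 higher), was lower by -0.87 ± 0.14, with 0.07 in experiment 1. The p53 target TP53INP1 (20 of 28 members of its list lower) was lower by -1.26 ± 0.21, with 0.06 in experiment 1. Its level was 4.79 in experiment 1 and 6.54 in experiments 2 and 3, so a fall in experiment 1 may be missed. The interferon-induced proteasome subunit PSMB9 (23 of 36 members lower) was lower by -0.94 ± 0.15, with 0.04 in experiment 1. PSMB9 was dim, with a mean of 4.38 over all 6 arrays against a median of 4.75 over all genes. The tight junction gene OCLN, on the list of epithelial junction and polarity genes (18 of 30 members lower), was lower by -0.71 ± 0.14, with -0.22 in experiment 1. Over all 6 arrays OCLN stood at -0.55 on this probe set and at 0.005 and -0.23 on other bright ones. DCP2, the mRNA decapping enzyme, which is on none of the lists, was lower by -1.32 ± 0.15, with -0.49 in experiment 1. Apart from OCLN, PFKFB3, DCP2 and XPO5, these genes were slightly higher in experiment 1.

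Without experiment 1 and with the block, 7 lists passed camera with a preset correlation, of which 6 moved down. They were the reported targets, cholesterol synthesis (adjusted p = 0.0023), p53 targets (0.012), the interferon response (0.018), endocytosis and clathrin adaptors (0.023) and TGF-beta and SMAD targets (0.045), and the G2 and mitosis list moved up. An estimated correlation was not run in this fit, and with all 6 arrays and the block it left 0 lists past the threshold.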
